A study of Gallus gallus with 15 samples.

How the data were processed

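Liver RNA was measured in 15 male chickens, 3 birds in each of 5 breeds, with 1 Affymetrix chicken gene array per bird. Each array was hybridised with biotin-labelled single-stranded cDNA. The deposited values are log2 expression values per feature, made by RMA (robust multi-array averaging, which normalises between arrays) in Affymetrix Expression Console 1.3.1, per the submitters' processing notes. The summarization level and the probe filter of that step are not stated. The table held 18308 features with 0 missing values, between 0.55 and 14.52 on the log2 scale, and all features were used. The scanner files and detection calls were not used here.

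Gene symbols came from the platform annotation. It gave exactly 1 symbol for 12300 features, several symbols for 256 and none for 5752, so 11528 distinct genes could be named. A list of current chicken gene names was checked for renamed symbols, and 0 symbols changed. For a gene with several features, the feature with the highest mean over the 15 arrays stood for it. No genome sequence was used. Probe positions, probes shared between gene copies and sequence differences between the breeds under the probes were therefore not checked.

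The breed means were fitted in 1 linear model of all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which leaves 10 residual degrees of freedom and adds 3.89 from the moderation of variances across features. Contrasts set each native breed against White Leghorn, the mean of the 4 native breeds against White Leghorn, and each native breed against the mean of the other 4 breeds. A moderated F test asked for any difference among the 5 breeds. A feature was called specific to a breed only if it passed against the mean of the other 4 breeds and, in the same direction, against each of them. P-values were adjusted by the Benjamini-Hochberg method over all 18308 features, a feature passed at an adjusted p under 0.05, and all tests were two-sided. Changes are differences of log2 means with the standard error of the model, and group values are means with the SD of 3 birds. The median standard error of a breed against White Leghorn was 0.15. The number of arrays limits the precision, and an exact permutation test of 3 birds against 3 cannot give a p below 0.1.

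The labels describe the arrays of a breed as biological replicates, so the p-values measure the spread between birds. No batch, date or scan group is given in the labels. The replicate numbers were checked as possible shared blocks and were not used in the model.

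Before the data were examined, 36 gene lists with 1308 symbols were fixed, covering liver metabolism, immune functions, cell-type markers, possible contamination and pigmentation. Of these symbols, 812 matched a measured gene. Some matched only through an older symbol, such as HSP25 to HSPB9, CALR to CALR3 and RPSA to RPSAP58. The 35 lists with at least 5 measured genes were tested with camera in limma, which asks whether a list is shifted against all other genes, at its preset correlation between genes of 0.01, with adjustment over the lists. The same test with a correlation estimated per list, and fry, which tests a list without comparing it with other genes, were run as alternatives. Members were also counted past the threshold over all features and adjusted over the list alone.

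The rule for named genes was also fixed before the data were examined. For each native breed against White Leghorn it takes the 4 largest rises and 4 largest falls among passing features whose 3 birds all lay on 1 side of the 3 White Leghorn birds, and up to 2 passing members in each direction from each list with a list call. It takes the 6 largest rises and falls for the native mean, the 3 largest in each direction among breed-specific genes, and the 5 largest F values. It also takes all measured genes of the EDN3 region, yolk precursor and W-linked lists, and the largest change in each cell-type list. Only features with a single symbol that is not a bare locus name could be named. Other list members given as examples, and other features outside the rule, were chosen after their values were seen.

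Alternatives to the model were variance moderation with trend and robust estimation, array weights, a further quantile normalisation, median centring of each array, and leaving out the third of features with the lowest means. Further alternatives were 1 feature per named gene, an added fold minimum of 1.5, only the 6 arrays of the compared breeds, an unadjusted p with a 2-fold change, lists of at least 10 genes, and leaving out each array in turn. Leaving out White Leghorn array 1 and Yeonsan Ogye array 1 together was chosen after seeing the data.

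The procedure was tested on simulated data with 200 of 18308 features changed in 1 breed and with noise drawn independently for each feature. In a comparison of 3 arrays with 3, it recovered 25.7% of features changed by 0.5 on the log2 scale, 82.4% of those changed by 1 and 99.1% of those changed by 2, and 6.39% of its calls were false. The F test recovered 19.1%, 81.8% and 98.5% at these sizes, with 4.74% false calls. Deviations of a bird common to many features were not simulated, so the shares for the real arrays may differ. The rule for breed-specific features was not tested this way.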

Results

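The livers of 13-week-old male chickens of 5 breeds were profiled with 1 array per bird and 3 birds per breed. White Leghorn (WL), an egg-laying breed used as the control, stood beside 4 native breeds of Korea. These were Hwangbong (coded Hw), Hoengseong Yakdak (Ya), Hyunin Black (Bl) and, as the last of them, Yeonsan Ogye (Og). Birds are named by code and replicate number, as in WL 1. The medians of the 15 arrays lay between 6.12 and 6.20 on the log2 scale, and correlations between arrays across features lay between 0.977 and 0.991. Of 3 measured genes of the female-specific W chromosome, HINTW had breed means between 4.16 and 4.41, UBAP2L2 between 2.20 and 2.57 and ATP5F1AW between 6.14 and 6.57. None passed over all features, whereas ATP5F1AW, at -0.43 ± 0.15 in Hoengseong Yakdak and -0.33 ± 0.12 in the native mean, was lower there adjusted over the list alone. No female array was at hand for comparison. Array background was not measured, and levels as low as that of HINTW in these males are not shown to be above it. Examples are APOV1, BDKRB1, C3ORF67, LRRTM4, PEX5L and MKI67 in White Leghorn, B-G, NXPH2 and MIR1803 in Yeonsan Ogye, B-G in Hoengseong Yakdak, ABCA12 in Hwangbong, and EDN3, TYRP1, VTG1 and VTG2 in every breed. The size of a change from or to such a level is a lower bound, and a difference between such levels shows nothing. The values that follow are log2 means with the SD of 3 birds, or log2 changes with the standard error of the model, and p-values are limma's, adjusted over all features unless a list is named.

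To ask which liver transcripts depended on breed at all, the 5 breed means were compared together. SIDT1, which encodes a membrane protein related to RNA transporters, stood at 7.59 ± 0.21 (SD, n = 3) in Hoengseong Yakdak and between 4.73 and 5.66 in the other breeds (F = 88.7, adjusted p = 1.81e-05). SLC7A10, a transporter of small neutral amino acids, was at 4.65 ± 0.53 in the same breed and between 6.49 and 7.19 elsewhere (F = 46.3, adjusted p = 0.000278; F = 105.9 without Ya 3). FBXO21, a ubiquitin-ligase subunit, ranged from 6.78 ± 0.14 in White Leghorn to 8.06 ± 0.05 in Hwangbong (F = 45.7, adjusted p = 0.000278). ENOX1, a cell-surface oxidase, was lowest in Hwangbong at 5.37 ± 0.27 and highest in Hoengseong Yakdak at 6.95 ± 0.09 (F = 37.4, adjusted p = 0.000634), and ATRNL1 had F = 38.9. In all, 293 of 18308 features differed among the breeds, 190 of them with a single symbol, and 2941 had an unadjusted p under 0.05. Between pairs of native breeds, 267 features differed between Hoengseong Yakdak and Hwangbong and 9 between Hyunin Black and Yeonsan Ogye. The count of 293 was 121 without Hw 2, 164 without Hw 3, 147 without Ya 2 and 176 without Ya 3.

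**Figure D1:**
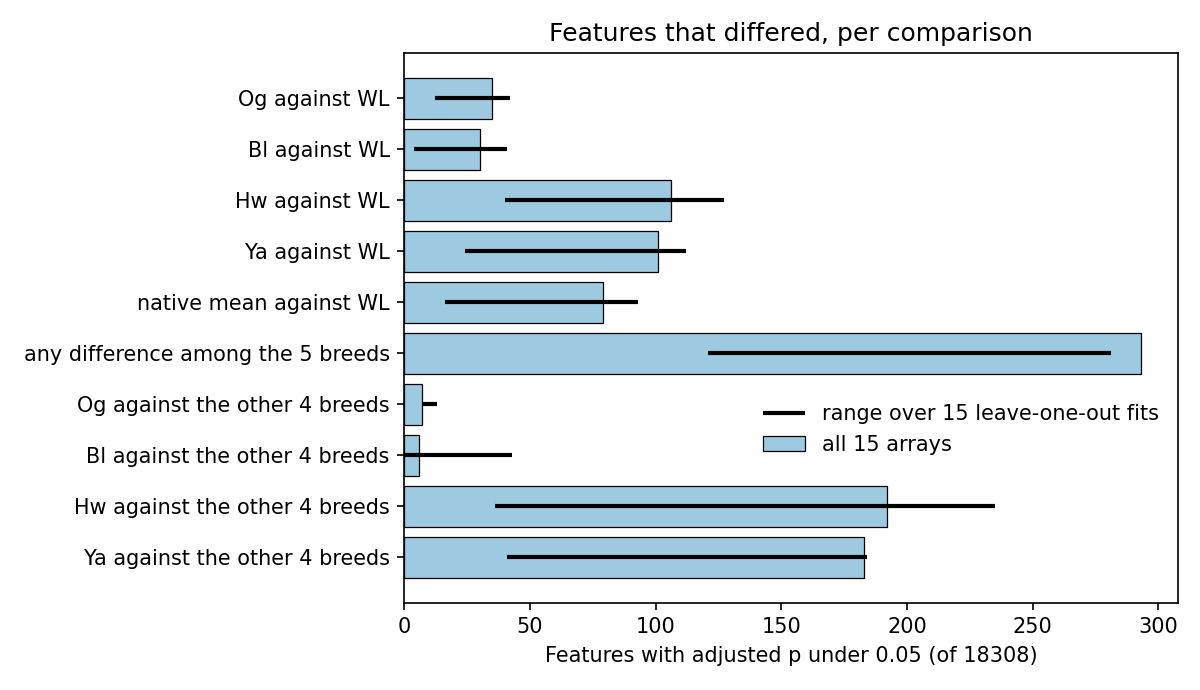
Number of features that differed (horizontal axis, adjusted p under 0.05, of 18308) in each comparison; bars use all 15 arrays and black lines span the fits that leave out 1 array each. The F test gave 293 features, Hwangbong against White Leghorn 106 and Hyunin Black against White Leghorn 30.

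Yeonsan Ogye was set against White Leghorn to ask how its liver differs from the control breed. APOV1, a protein of yolk lipoprotein particles that liver makes under estrogen, rose from 4.24 ± 0.30 to 6.98 ± 0.74 (SD, n = 3), a change of 2.74 ± 0.50 (adjusted p = 0.0429). CRLF2, a receptor subunit for the cytokine TSLP, rose by 2.34 ± 0.25 (adjusted p = 0.00181). TP53INP1, a p53-induced stress and autophagy protein, rose by 1.24 ± 0.17 (adjusted p = 0.0101), and C3ORF67 by 1.94 ± 0.28 (adjusted p = 0.0148). B-G, a butyrophilin-like gene of the chicken MHC, fell by 4.49 ± 0.72 (adjusted p = 0.0234). It belongs to a family of near-identical copies, so which copy its probes read is uncertain. NXPH2, a neurexophilin, fell by 1.55 ± 0.22 (adjusted p = 0.0146). ZC3H12C, a member of a family of RNA-degrading zinc-finger proteins, fell by 1.25 ± 0.21 (adjusted p = 0.0317), and RAB23, a small GTPase of hedgehog signalling, fell by 1.19 ± 0.19 (adjusted p = 0.0227). In all, 35 features differed, 19 higher and 16 lower, 23 with a single symbol, and 1673 had an unadjusted p under 0.05. The count was 23 without WL 1, 17 without WL 2, 14 without WL 3, 20 without Og 2, 12 without Og 3 and 23 without Hw 3. CRLF2 and TP53INP1 passed in every fit with 1 array left out. NXPH2 was lost without Og 3 (adjusted p = 0.0525), C3ORF67 without WL 2, WL 3 or Og 3 (up to 0.0553) and RAB23 without WL 1, WL 2, Og 2 or Og 3 (up to 0.0775). B-G was lost without WL 1, WL 2 or any Og bird (up to 0.0942) and ZC3H12C without Hw 3 or any WL or Og bird (up to 0.127). APOV1 passed only without Og 1, Bl 2, Bl 3 or Ya 1 (adjusted p up to 0.166 otherwise).

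The EDN3 region list holds genes around endothelin 3, a segment that is duplicated in chickens with dermal hyperpigmentation. The 7 measured genes lay above White Leghorn in Yeonsan Ogye, although for EDN3 both levels, 4.35 and 4.41, are not shown to be above background. The list mean, relative to all 15 arrays, was 0.40 ± 0.07 (SD, n = 3) against -0.15 ± 0.11. ATP5E, a subunit of ATP synthase, rose from 9.23 ± 0.15 to 10.24 ± 0.14, a change of 1.01 ± 0.16 (adjusted p = 0.0234). PRELID3B changed by 1.11 ± 0.31 (adjusted p = 0.218), TUBB1 by 0.77 ± 0.24 (adjusted p = 0.303) and ZNF831 by 0.67 ± 0.17 (adjusted p = 0.165), and none of these passed over all features. CTSZ changed by 0.10 ± 0.09 and NELFCD by 0.12 ± 0.13. In Hyunin Black, where the list was not called (camera adjusted p = 0.113), 6 of 7 lay above 0, with TUBB1 at 0.72 ± 0.24. Over all features 1 member rose and 0 fell; adjusted over the list alone, 4 rose and 0 fell. The list passed camera (adjusted p = 1.56e-05) and held at adjusted p = 0.0172 with an estimated correlation, the only one of 37 list calls in the 5 comparisons with White Leghorn that did. The list passed in all 15 fits with 1 array left out, whereas ATP5E was lost without any 1 of the WL or Og birds (adjusted p up to 0.0884).

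**Figure D2:**
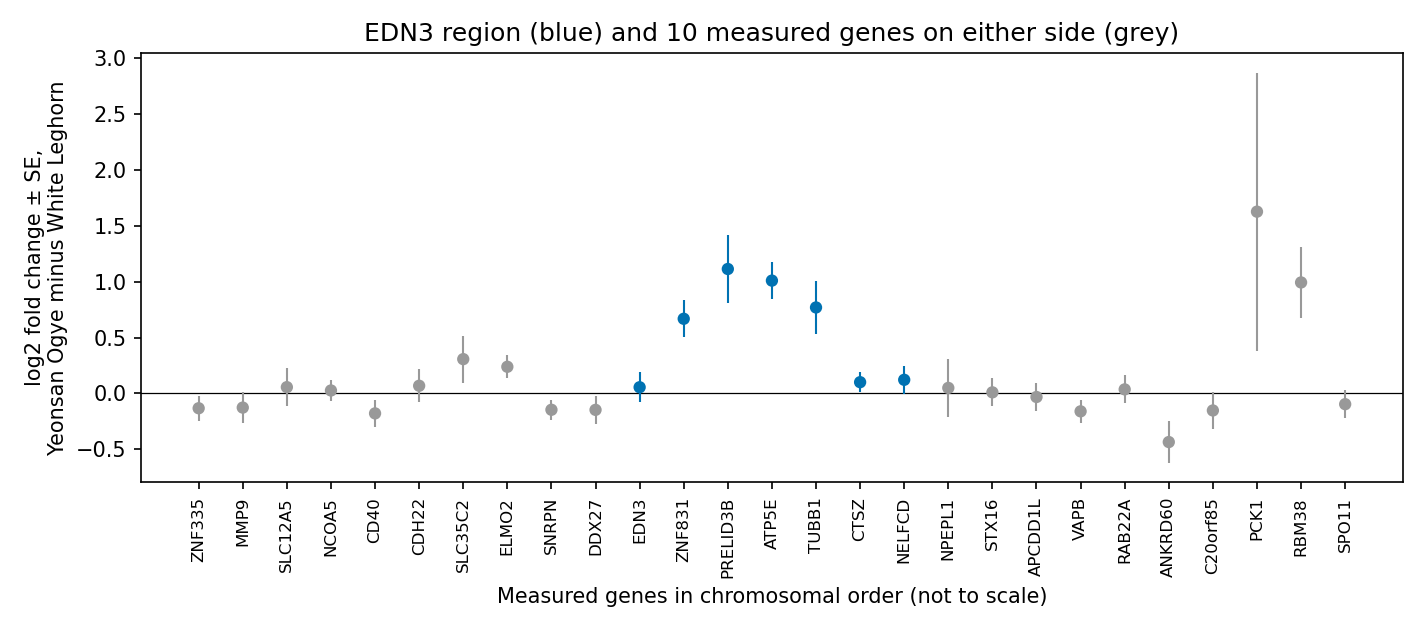
Log2 change in Yeonsan Ogye against White Leghorn (vertical axis, points with standard errors) for the 7 measured EDN3 region genes, in blue, and 10 measured genes on either side, in grey, in chromosomal order. ATP5E stands at 1.01 and PRELID3B at 1.11, while CTSZ and NELFCD lie at 0.10 and 0.12; EDN3, at 0.06, has levels that are not shown to be above background.

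Genes of fatty acid and triglyceride synthesis lay higher in Yeonsan Ogye in 16 of 16 measured members, with a mean change of 0.54 (0.343 without WL 1). The list means of the WL birds were spread, at -0.738, -0.267 and -0.015, and Og 1, at -0.004, lay close to WL 3. ME1, the malic enzyme that supplies NADPH for lipid synthesis, changed by 2.05 ± 0.54, FADS1 by 0.78 ± 0.21 and ELOVL6 by 0.66 ± 0.18. Adjusted over the list alone these 3 rose and 0 fell, and over all features 0 passed. Camera gave adjusted p = 6.14e-06, and adjusted p = 0.433 with an estimated correlation. Cholesterol synthesis and uptake had 12 of 14 members above 0, with SQLE at 0.89 ± 0.43 and 0 members passing over all features or adjusted over the list alone (camera adjusted p = 0.0178; adjusted p = 0.799 with an estimated correlation). Amino acid catabolism had 28 of 37 members below 0. GLDC, of glycine cleavage, changed by -1.18 ± 0.29 and KMO by -0.46 ± 0.12, the 2 that fell adjusted over the list alone, and 0 passed over all features (camera adjusted p = 5.43e-05; adjusted p = 0.433 with an estimated correlation). Purine and uric acid synthesis had 18 of 23 members below 0. ADSL changed by -1.18 ± 0.26 and XDH, which makes uric acid, by -1.15 ± 0.22, both lower adjusted over the list alone with 0 passing over all features (camera adjusted p = 0.00165; adjusted p = 0.669 with an estimated correlation). Acute phase and complement had 20 of 30 members below 0, with 1 lower adjusted over the list alone, MASP2 at -0.78 ± 0.17, and 0 over all features (camera adjusted p = 0.012; adjusted p = 0.742 with an estimated correlation). Heat shock and handling stress had 24 of 31 members below 0. Adjusted over the list alone HSPB9 and DNAJA1 fell and SGK1 and MYC rose, and 0 passed over all features (camera adjusted p = 0.012; adjusted p = 0.742 with an estimated correlation). The interferon response had 24 of 32 members below 0, with IFI6 at -0.95 ± 0.54 and 0 passing over all features or adjusted over the list alone (camera adjusted p = 0.0353; adjusted p = 0.838 with an estimated correlation). Fatty acid synthesis, amino acid catabolism and purine synthesis passed in every fit with 1 array left out. Cholesterol synthesis was lost without WL 1, WL 2 or Og 3 (adjusted p up to 0.58), acute phase without WL 3 or Og 1 (up to 0.191). Heat shock was lost without WL 1 or Og 3 (up to 0.345) and interferon without WL 2, WL 3 or Og 1 (up to 0.489). The mean change of cholesterol synthesis, 0.422 with all arrays, was 0.135 without WL 1, 0.152 without Og 3, 0.664 without Og 1 and 0.81 without WL 3. That of heat shock, -0.209, was -0.0659 without WL 1 and -0.321 without WL 3, and that of interferon, -0.242, was -0.116 without Og 1.

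Hyunin Black was compared with White Leghorn in the same way. APOV1 rose by 3.03 ± 0.50 (adjusted p = 0.027), from 4.24 ± 0.30 to 7.27 ± 1.21 (SD, n = 3). C3ORF67 rose by 1.90 ± 0.28 (adjusted p = 0.02), NSMF, a protein of synapse-to-nucleus signalling, by 1.81 ± 0.33 (adjusted p = 0.0444), and the feature annotated as the microRNA gene MIR1719 by 1.37 ± 0.19 (adjusted p = 0.0146). CAPSL, a calcium-binding calcyphosine-like protein, fell by 2.78 ± 0.36 (adjusted p = 0.0146), from 8.94 ± 0.28 to 6.16 ± 0.09. HSPB9, a small heat shock protein, fell by 1.96 ± 0.33 (adjusted p = 0.027), ADAMTS17, a matrix metalloprotease, fell by 1.57 ± 0.28 (adjusted p = 0.0463), and NXPH2 fell by 1.28 ± 0.22 (adjusted p = 0.0382). In all, 30 features differed, 16 higher and 14 lower, 19 with a single symbol, and 2151 had an unadjusted p under 0.05. The count was 16 without WL 1, 11 without WL 3, 17 without Bl 1 and 4 without Bl 3. CAPSL and MIR1719 were lost only without Bl 3 (adjusted p = 0.0557 and 0.0619), C3ORF67 without any WL bird, Bl 1 or Bl 3 (up to 0.0798), APOV1 without any WL bird, Bl 1 or Bl 2 (up to 0.0888). HSPB9 was lost without WL 1, WL 3 or any Bl bird (up to 0.108). NXPH2 was lost in all fits but those without WL 3, Og 1 or Bl 2 (up to 0.123), NSMF in all but those without Og 1, Og 3 or Bl 1 (up to 0.145) and ADAMTS17 in all but those without WL 1, Ya 2 or Ya 3 (up to 0.149).

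The interferon response list lay higher in Hyunin Black in 30 of 32 measured genes, with a mean change of 0.73 (0.381 without Bl 1). IFI6 changed by 1.96 ± 0.54, CMPK2, an antiviral nucleotide kinase, by 1.58 ± 0.46, MX1 by 1.49 ± 0.58 and RSAD2 by 1.46 ± 0.52. Over all features 0 passed (22 at an unadjusted p under 0.05 in limma); adjusted over the list alone, 21 rose and 0 fell (camera adjusted p = 4.47e-13; adjusted p = 0.564 with an estimated correlation). The list means of the birds were 1.26 in Bl 1, -0.09 in Bl 2 and 0.48 in Bl 3, so the spread within the breed exceeded its distance from White Leghorn. T and NK cell markers had 17 of 22 members above 0. UBASH3A, at 0.53 ± 0.15, and 1 other gene rose adjusted over the list alone and 0 passed over all features (camera adjusted p = 0.00777; adjusted p = 0.564 with an estimated correlation). Fatty acid and triglyceride synthesis had 14 of 16 members above 0. ME1 at 1.68 ± 0.54, FADS1 at 0.84 ± 0.21 and ELOVL6 at 0.59 ± 0.18 were the 3 that rose adjusted over the list alone, with 0 over all features (camera adjusted p = 0.000862; adjusted p = 0.564 with an estimated correlation). Ribosomal proteins had 38 of 51 members below 0, such as RPS29 at -0.35 ± 0.12, with 0 passing either way (camera adjusted p = 0.00279; adjusted p = 0.628 with an estimated correlation). Amino acid catabolism had 26 of 37 members below 0, such as HAL at -0.99 ± 0.35, with 0 passing either way (camera adjusted p = 0.00982; adjusted p = 0.564 with an estimated correlation). Heat shock and handling stress had 21 of 31 members below 0, of which HSPB9 fell both over all features and adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.628 with an estimated correlation). Amino acid catabolism was lost without WL 2 or Bl 3 (adjusted p up to 0.117) and heat shock without WL 1, Bl 1 or Bl 3 (up to 0.221), and the other 4 lists passed in every fit with 1 array left out, although the mean change of fatty acid synthesis went from 0.478 to 0.279 without WL 1. That of amino acid catabolism, -0.164, was -0.101 without Bl 3, and that of heat shock, -0.206, was -0.0636 without WL 1, -0.0693 without Bl 3, -0.318 without WL 3 and -0.356 without Bl 2.

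Hwangbong, compared with White Leghorn, showed its largest rises in LRRTM4, NSMF, MAOA and TLR2. TLR2, a receptor for bacterial lipoproteins, rose by 1.65 ± 0.22 (adjusted p = 0.00388), from 5.21 ± 0.40 to 6.86 ± 0.31 (SD, n = 3). LRRTM4, a synaptic adhesion protein, rose by 1.87 ± 0.34 (adjusted p = 0.027), NSMF by 1.79 ± 0.33 (adjusted p = 0.0261) and MAOA, a monoamine oxidase, by 1.72 ± 0.35 (adjusted p = 0.0435). ROBO1, a receptor for SLIT guidance cues, fell by 2.75 ± 0.44 (adjusted p = 0.0116), SULT, a sulfotransferase, fell by 2.83 ± 0.52 (adjusted p = 0.0261). ABCA12, a lipid transporter, fell by 2.65 ± 0.54 (adjusted p = 0.0453) and B-G fell by 3.86 ± 0.72 (adjusted p = 0.0308). LIPC, the hepatic lipase, fell by 2.63 ± 0.36 (adjusted p = 0.00459), NDUFA8, of respiratory complex I, fell by 1.28 ± 0.18 (adjusted p = 0.00459) and STC2 fell by 1.89 ± 0.36 (adjusted p = 0.0352). These 3 were chosen after their values were seen, and STC2 was lost without WL 1, WL 3, Bl 3, Hw 1 or Hw 2 (adjusted p up to 0.142). In all, 106 features differed, 62 higher and 44 lower, 71 with a single symbol, and 2355 had an unadjusted p under 0.05. The count was 57 without WL 1, 67 without WL 3, 40 without Hw 2 and 59 without Hw 3. ROBO1 and TLR2 passed in every fit with 1 array left out. LRRTM4 was lost without any WL bird, Hw 1 or Hw 2 (adjusted p up to 0.0904), NSMF without any WL or Hw bird (up to 0.0951), SULT without WL 2, WL 3 or any Hw bird (up to 0.0981). B-G was lost without WL 1, WL 2 or any Hw bird (up to 0.109). MAOA was lost in all fits but those without WL 3, Og 1, Og 2 or Hw 1 (up to 0.164) and ABCA12 in all but those without WL 3, Og 1 or Ya 1 (up to 0.169).

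Lists of the interferon response, of T and NK cells, macrophages and endothelium and of the cell cycle were called higher in Hwangbong, and all 5 calls were lost with an estimated correlation (adjusted p = 0.721 to 0.786). Acute phase and complement was called lower (adjusted p = 0.726 with an estimated correlation). Among immune lists that were not called, antigen presentation had 11 of 15 members above 0 (camera adjusted p = 0.0865) and heterophil markers had 10 of 13 below 0 (camera adjusted p = 0.0865). The interferon response had 31 of 32 members above 0, and LY6E, an interferon-induced membrane protein, rose by 1.09 ± 0.19 (adjusted p = 0.0247), the 1 member past the threshold over all features. Adjusted over the list alone 3 rose and 0 fell, with GBP4L at 1.02 ± 0.27 (camera adjusted p = 1.25e-07; adjusted p = 0.721 with an estimated correlation). T and NK cell markers had 17 of 22 members above 0. UBASH3A, a regulator of T-cell signalling, rose by 0.72 ± 0.15 (adjusted p = 0.0472), and 2 members rose adjusted over the list alone (camera adjusted p = 0.000356; adjusted p = 0.721 with an estimated correlation). Macrophage markers had 13 of 17 members above 0. Adjusted over the list alone 4 rose, among them C1QC at 0.56 ± 0.17, and 1 fell, LYZ at -0.66 ± 0.20, with 0 over all features (camera adjusted p = 0.0292; adjusted p = 0.721 with an estimated correlation). Endothelial markers had 13 of 18 members above 0 and 5 that rose adjusted over the list alone, such as PECAM1 at 0.55 ± 0.13, with 0 over all features (camera adjusted p = 0.0148; adjusted p = 0.721 with an estimated correlation). Cell cycle genes had 24 of 32 members above 0, with MKI67 at 0.82 ± 0.30 and 0 passing either way (camera adjusted p = 0.0165; adjusted p = 0.786 with an estimated correlation). Interferon, T and NK cell and endothelial lists passed in every fit with 1 array left out. LY6E was lost without any WL bird, Hw 2 or Hw 3 (adjusted p up to 0.108) and UBASH3A in all fits but those without Og 1, Ya 2 or Ya 3 (up to 0.154). The macrophage list was lost without WL 3 or Hw 3 (up to 0.1) and the cell cycle list without WL 2, Hw 1 or Hw 3 (up to 0.159).

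Lists of metabolism, stress and hepatocyte markers were also called in Hwangbong. Antioxidant and NRF2 targets had 24 of 29 members above 0, with SOD2 at 0.52 ± 0.20 and 0 passing either way (camera adjusted p = 0.0094; adjusted p = 0.721 with an estimated correlation). Fatty acid and triglyceride synthesis had 13 of 16 above 0, with ME1 at 1.38 ± 0.54 and 0 passing either way (camera adjusted p = 0.0358; adjusted p = 0.721 with an estimated correlation). Amino acid catabolism had 29 of 37 below 0, and KMO, at -0.55 ± 0.12, was the 1 lower gene adjusted over the list alone, with 0 over all features (camera adjusted p = 0.0165; adjusted p = 0.721 with an estimated correlation). Heat shock and handling stress had 27 of 31 below 0, and HSPB9, at -1.38 ± 0.33, was the 1 lower gene adjusted over the list alone, with 0 over all features (camera adjusted p = 0.0094; adjusted p = 0.721 with an estimated correlation). Acute phase and complement had 20 of 30 below 0, such as LECT2 at -0.93 ± 0.63 (camera adjusted p = 0.0404; adjusted p = 0.726 with an estimated correlation). Hepatocyte markers had 22 of 31 below 0, with AGXT2 at -0.69 ± 0.32 (camera adjusted p = 0.0301; adjusted p = 0.721 with an estimated correlation), and muscle and adipose markers 9 of 14 (camera adjusted p = 0.0352; adjusted p = 0.721 with an estimated correlation). In these 3 lists 0 members passed either way. The antioxidant list passed in every fit with 1 array left out. Fatty acid synthesis was lost without WL 1, Hw 1 or Hw 3 (adjusted p up to 0.66), amino acid catabolism without WL 2 or Hw 1 (up to 0.377). Heat shock was lost without WL 1 or Hw 3 (up to 0.18), acute phase without WL 2, WL 3 or any Hw bird (up to 0.336), and hepatocyte markers without WL 2, WL 3 or Hw 1 (up to 0.422) and muscle and adipose markers without WL 1, Hw 2 or Hw 3 (up to 0.369). Without WL 1 the mean change went from 0.28 to 0.0812 for fatty acid synthesis, from -0.306 to -0.163 for heat shock and from -0.155 to -0.0614 for muscle and adipose markers. Without Hw 1 it went from -0.182 to -0.116 for amino acid catabolism and from -0.0978 to -0.0497 for hepatocyte markers, and without WL 3 fatty acid synthesis stood at 0.443.

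**Figure D3:**
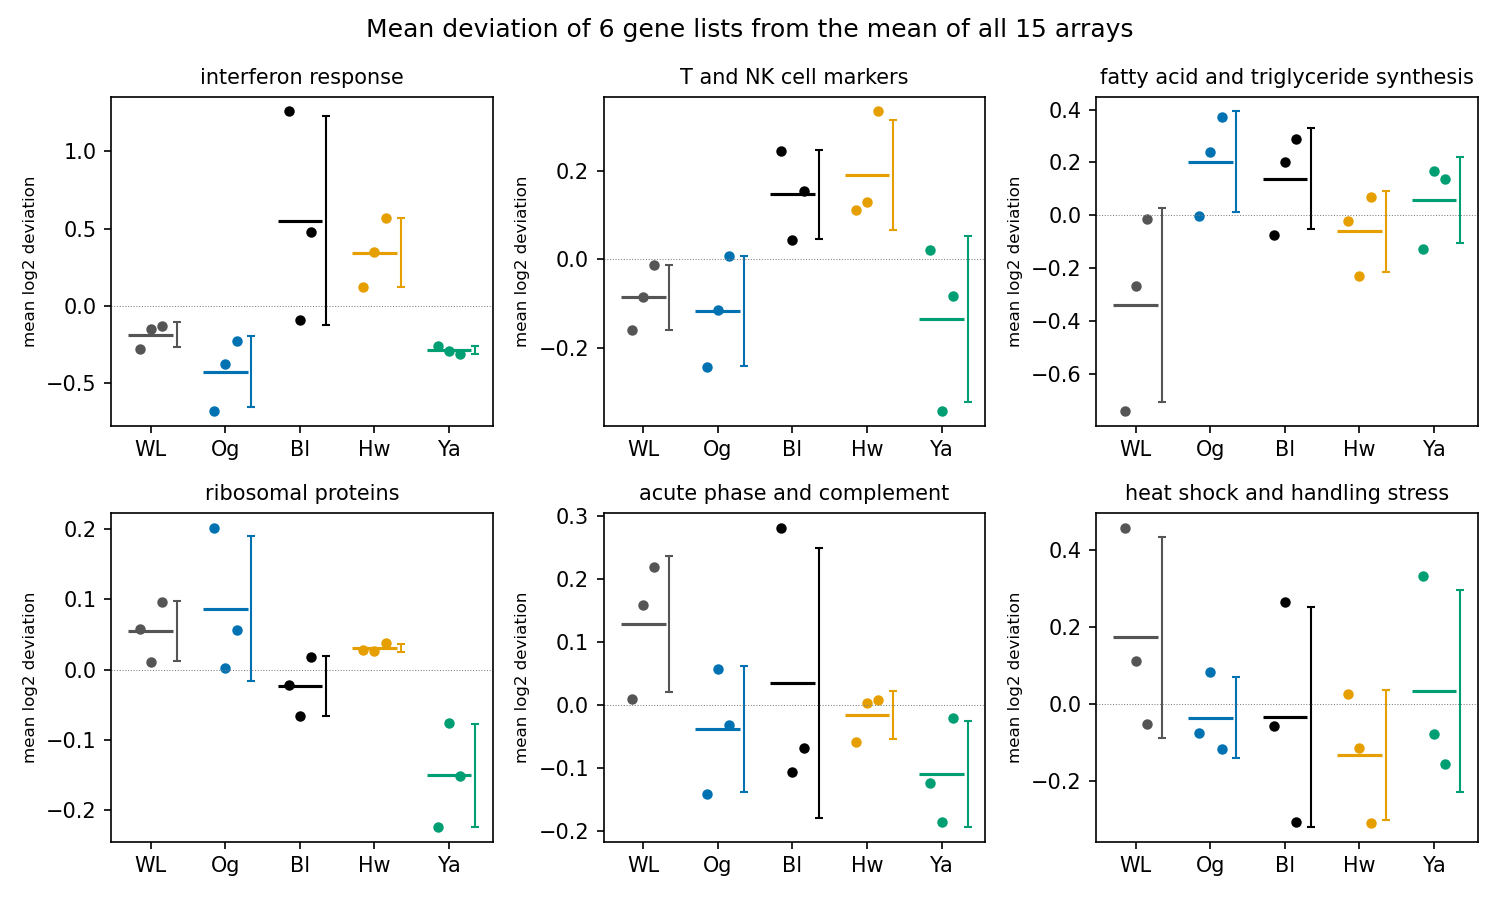
Mean log2 deviation of 6 gene lists from the mean of all 15 arrays (vertical axis) for each bird (points) in the 5 breeds, with breed means (lines) and SD (bars). The interferon response list stands at 1.26, -0.09 and 0.48 in the 3 Bl birds and at -0.28, -0.15 and -0.13 in the 3 WL birds.

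Hoengseong Yakdak was likewise compared with White Leghorn. BDKRB1, a bradykinin receptor, rose by 3.53 ± 0.46 (adjusted p = 0.00371), from 4.33 ± 0.34 to 7.86 ± 0.20 (SD, n = 3). SIDT1 rose by 2.34 ± 0.17 (adjusted p = 2.34e-05), ATRNL1, an attractin-like protein, by 2.06 ± 0.22 (adjusted p = 0.000543) and DBNDD2, a dysbindin-domain protein, by 1.44 ± 0.15 (adjusted p = 0.000543). B-G fell by 4.71 ± 0.72 (adjusted p = 0.0118), SLC7A10 fell by 2.25 ± 0.21 (adjusted p = 0.000233). CORO2A, an actin-binding coronin, fell by 1.94 ± 0.33 (adjusted p = 0.0216) and ADAMTS17 fell by 1.82 ± 0.28 (adjusted p = 0.0118). In all, 101 features differed, 53 higher and 48 lower, 63 with a single symbol, and 2338 had an unadjusted p under 0.05. The count was 56 without WL 1, 59 without WL 2, 59 without WL 3, 24 without Ya 2 and 44 without Ya 3. BDKRB1, SIDT1, ATRNL1, DBNDD2 and SLC7A10 passed in every fit with 1 array left out. B-G and ADAMTS17 were lost only without Ya 2 (adjusted p = 0.0535 and 0.0615) and CORO2A without WL 1, WL 3 or any Ya bird (up to 0.0845).

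Ribosomal protein genes lay lower in Hoengseong Yakdak in 49 of 51 measured members, with a mean change of -0.21. RPL23A changed by -0.57 ± 0.12 (adjusted p = 0.0506), RPL23 by -0.45 ± 0.13 and RPL27A by -0.43 ± 0.11. Adjusted over the list alone 10 fell and 0 rose, and over all features 0 passed (20 at an unadjusted p under 0.05 in limma). Camera gave adjusted p = 8.89e-14, and adjusted p = 0.781 with an estimated correlation. Acute phase and complement had 26 of 30 members below 0. IL1R1 at -1.40 ± 0.42, C8A at -0.59 ± 0.18 and C4 at -0.47 ± 0.14 were the 3 that fell adjusted over the list alone, with 0 over all features (camera adjusted p = 1.55e-05; adjusted p = 0.781 with an estimated correlation). Fatty acid and triglyceride synthesis had 14 of 16 members above 0. ME1 at 2.01 ± 0.54 and ELOVL6 at 0.72 ± 0.18 rose adjusted over the list alone, with 0 over all features (camera adjusted p = 0.0105; adjusted p = 0.838 with an estimated correlation). Bile duct markers had 11 of 15 members above 0, and BICC1, an RNA-binding protein, rose by 0.75 ± 0.12 (adjusted p = 0.0169). DCDC2 at 1.00 ± 0.24 and CDH1 at 0.47 ± 0.11 made up the 3 that rose adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.781 with an estimated correlation). The list means were 0.333 and 0.306 in Ya 2 and Ya 3, whereas Ya 1, at -0.075, lay below all 3 WL birds (-0.009, -0.068 and -0.041), and the mean change went from 0.227 to 0.359 without Ya 1. Stellate, fibroblast and matrix markers, which were not called, stood at -0.358, 0.35 and 0.326 in Ya 1, Ya 2 and Ya 3. The ribosomal and acute phase lists passed in every fit with 1 array left out. Fatty acid synthesis was lost without WL 1 or Ya 2 (adjusted p up to 0.235; mean change 0.399, and 0.2 without WL 1), the bile duct list without Ya 2 (adjusted p = 0.227) and BICC1 without WL 2, WL 3, Ya 2 or Ya 3 (up to 0.079). The number of lists called in Hoengseong Yakdak was 4, and it was 7 without Ya 1 and 2 without Ya 2. In Hyunin Black it was 6, and 11 without WL 3 and 10 without Bl 1, and in Hwangbong it was 12, and 6 without Hw 3.

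The mean of the 4 native breeds was set against White Leghorn. This contrast has the same form as 1 breed against the other 4. It cannot tell what the native breeds share from what is particular to the 3 WL birds. Contrasts of this form gave 7 features in Yeonsan Ogye, 6 in Hyunin Black, 192 in Hwangbong and 183 in Hoengseong Yakdak. COMTD1, a catechol methyltransferase-like enzyme, rose by 1.94 ± 0.34 (adjusted p = 0.0304), from 9.51 ± 1.3 (SD, n = 3) to breed means between 11.25 and 11.58. APOV1 rose by 1.95 ± 0.39 (adjusted p = 0.0497), although its mean in Hwangbong, 4.29 ± 0.07, was close to that in White Leghorn. LRRTM4 rose by 1.59 ± 0.27 (adjusted p = 0.0261), NSMF by 1.41 ± 0.26 (adjusted p = 0.0314), with a lower mean in Yeonsan Ogye (5.91) than in the other native breeds (6.87 to 7.19). C3ORF67 rose by 1.15 ± 0.23 (adjusted p = 0.0443), with means of 5.94 and 5.90 in Yeonsan Ogye and Hyunin Black but 4.53 and 4.21 in Hwangbong and Hoengseong Yakdak, against 3.996 in White Leghorn, and the feature annotated as the microRNA gene MIR1719 by 1.04 ± 0.15 (adjusted p = 0.012). B-G fell by 4.0 ± 0.57 (adjusted p = 0.0124), HSPB9 fell by 1.58 ± 0.26 (adjusted p = 0.0194), ADAMTS17 fell by 1.58 ± 0.22 (adjusted p = 0.0124). TPPP, a tubulin-polymerising protein, fell by 1.57 ± 0.25 (adjusted p = 0.0187), LIPC fell by 1.42 ± 0.29 (adjusted p = 0.0497), to 6.44 in Hwangbong and between 7.84 and 8.27 in the other native breeds, and NXPH2 fell by 1.29 ± 0.18 (adjusted p = 0.0104). In all, 79 features differed, 37 higher and 42 lower, 48 with a single symbol, and 2229 had an unadjusted p under 0.05. The count was 16 without WL 1, 24 without WL 2, 17 without WL 3, 44 without Bl 3, 35 without Hw 2, 34 without Hw 3 and 44 without Ya 2. Of these genes NXPH2 alone passed in every fit with 1 array left out. ADAMTS17 was lost without WL 2 or WL 3 (adjusted p up to 0.0656), MIR1719 without WL 1 or WL 3 (up to 0.0722), B-G without WL 1 or WL 2 (up to 0.0823). TPPP was lost without WL 1 or WL 2 (up to 0.103), LRRTM4 without any WL bird (up to 0.103), HSPB9 without WL 1 or WL 3 (up to 0.117). COMTD1 was lost without WL 1, WL 2, Bl 3, Hw 2 or Hw 3 (up to 0.144), NSMF without any WL bird, Bl 3, Hw 2, Hw 3 or Ya 2 (up to 0.154). LIPC was lost in all fits but those without Bl 1, Bl 3 or Hw 1 (up to 0.174), C3ORF67 in all but those without Og 1 or Og 2 (up to 0.185) and APOV1 in all but those without Og 1, Bl 2 or Bl 3 (up to 0.189).

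Among the lists, fatty acid and triglyceride synthesis lay higher in the native mean in 16 of 16 members. ME1 changed by 1.78 ± 0.43, ELOVL1 by 0.64 ± 0.21 and ELOVL6 by 0.57 ± 0.14, the 3 that rose adjusted over the list alone, with 0 over all features (camera adjusted p = 0.000136; adjusted p = 0.7 with an estimated correlation). Amino acid catabolism had 27 of 37 members below 0. HAL at -1.01 ± 0.28, GLDC at -0.78 ± 0.23 and KMO at -0.40 ± 0.09 fell adjusted over the list alone, with 0 over all features (camera adjusted p = 0.00334; adjusted p = 0.7 with an estimated correlation). Acute phase and complement had 24 of 30 below 0. IL1R1 at -1.13 ± 0.33, MASP2 at -0.46 ± 0.13 and CFI at -0.31 ± 0.08 fell adjusted over the list alone, with 0 over all features (camera adjusted p = 0.00143; adjusted p = 0.7 with an estimated correlation). Ribosomal proteins had 40 of 51 below 0, with RPL23A at -0.41 ± 0.09 the 1 lower gene adjusted over the list alone and 0 over all features (camera adjusted p = 0.00143; adjusted p = 0.758 with an estimated correlation). The breeds differed in this list, with mean changes of -0.205 in Hoengseong Yakdak, -0.0781 in Hyunin Black, -0.0242 in Hwangbong and 0.0316 in Yeonsan Ogye, where 33 of 51 lay above 0. Heat shock and handling stress had 25 of 31 below 0, with HSPB9 lower over all features and adjusted over the list alone (camera adjusted p = 0.00334; adjusted p = 0.7 with an estimated correlation). The list means of the WL birds were 0.458, 0.111 and -0.052, and the mean change of -0.215 was -0.0725 without WL 1 and -0.327 without WL 3. The interferon response had 29 of 32 above 0, with DTX3L at 0.53 ± 0.15 (camera adjusted p = 0.00465; adjusted p = 0.763 with an estimated correlation), and muscle and adipose markers 11 of 14 below 0 (camera adjusted p = 0.0452; adjusted p = 0.7 with an estimated correlation). In these 2 lists 0 members passed either way. The interferon list lay higher in Hyunin Black and Hwangbong alone, with mean changes of 0.735 and 0.529 (adjusted p = 0.564 and 0.721 with an estimated correlation). In Yeonsan Ogye it was called lower (adjusted p = 0.838 with an estimated correlation), with a mean change of -0.242 that was -0.116 without Og 1, where the call was lost (adjusted p = 0.489), and in Hoengseong Yakdak, at -0.101, 21 of 32 members lay below 0. Its native mean change of 0.23 was 0.142 without Bl 1. Each of the 7 calls was lost in at least 1 fit with 1 array left out. Fits without a WL bird hold fewer control birds, so such a loss alone does not show that 1 array made the call. Fatty acid synthesis was lost without WL 1 (adjusted p = 0.0517), as were interferon (0.0571) and heat shock (0.217). Acute phase and ribosomal proteins were lost without WL 3 (0.0573 each), amino acid catabolism without WL 2 (0.0594) and muscle and adipose markers without WL 1, Og 3, Bl 3, Hw 2, Hw 3, Ya 1 or Ya 3 (up to 0.498). Without WL 1 the mean change of fatty acid synthesis went from 0.425 to 0.226 and that of muscle and adipose markers from -0.119 to -0.0261 (-0.181 without WL 2). Without WL 1, 4 lists were called.

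Features shared by the 4 comparisons with White Leghorn were counted next. NXPH2 fell in all 4, with changes of -1.55 ± 0.22 in Yeonsan Ogye, -1.28 ± 0.22 in Hyunin Black, -1.26 ± 0.22 in Hwangbong and -1.08 ± 0.22 in Hoengseong Yakdak. NAALAD2, a peptidase chosen after its values were seen, rose in all 4, by 0.73, 0.79, 1.43 and 0.70 in the same order (adjusted p = 0.0317, 0.027, 0.000191 and 0.0254). These 2 genes and 2 features without a symbol were called in the same direction in all 4 comparisons, and 40 features in at least 2. Any pair of comparisons shared 8 to 17 features, where independent comparisons would share 0.0288 to 0.295. In 100 simulations of unchanged breeds, with all 15 arrays drawn anew, at most 0 features were shared by all 4 comparisons and at most 1 by 2 or more. Unchanged breeds give almost no calls to share, so these counts cannot tell breed differences from deviations of the shared White Leghorn birds. Correlations of changes between comparisons lay between 0.44 and 0.587 across features, which are not independent replicates, against 0.499 to 0.501 in the simulations, and covariances between 0.0375 and 0.0475 against 0.0208 to 0.0209. The 3 WL arrays cannot be split into 2 groups of 2 birds, so part of the sharing may come from the shared controls. The count of 40 was 18 without WL 1, 26 without WL 2, 18 without WL 3, 25 without Bl 3, 22 without Hw 2, 24 without Hw 3 and 26 without Ya 2. NAALAD2 passed in Hwangbong in every fit with 1 array left out. It was lost in Yeonsan Ogye without WL 2, WL 3, Og 2, Og 3, Bl 3, Hw 3 or Ya 3 (adjusted p up to 0.141), in Hyunin Black without WL 2, WL 3, Bl 1 or Bl 3 (up to 0.0866) and in Hoengseong Yakdak without WL 2, WL 3, Ya 2 or Ya 3 (up to 0.112). NXPH2 was lost in Hwangbong without WL 1 or any Hw bird (up to 0.096) and in Hoengseong Yakdak in all fits but those without WL 3, Bl 2 or Bl 3 (up to 0.146).

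The stated aim of breed-specific expression was addressed by setting each native breed against the other 4. Sequence differences between the breeds under the probes were not checked, so the values are array signals that may differ from transcript levels. In Yeonsan Ogye, CRLF2 rose by 2.34 ± 0.20 (adjusted p = 9.79e-05) and the feature annotated as the microRNA gene MIR1803 fell by 1.14 ± 0.12 (adjusted p = 0.000678). These and 1 feature without a symbol passed against every other breed, out of 7 features that differed from their mean, 5 higher and 2 lower, with 1459 at an unadjusted p under 0.05. ATP5E rose by 0.97 ± 0.13 and PLBD1, a phospholipase-like protein, fell by 0.85 ± 0.12 against that mean; both were chosen after their values were seen. In Hyunin Black 6 features differed from the mean of the other 4 breeds, 1 higher and 5 lower, with 1681 at an unadjusted p under 0.05, and limma called 0 specific to the breed. The named ones, chosen after their values were seen, were CAPSL at -2.32 ± 0.29, PLET1 at -1.35 ± 0.21, GIMD1 at -1.15 ± 0.17 and DCTD, a deoxycytidylate deaminase, at -0.75 ± 0.11. Without 1 array, the Yeonsan Ogye count was 13 (Og 1) or 12 (Ya 3). The Hyunin Black count was 14 (Og 1), 13 (Og 3), 3 (Bl 1), 43 (Bl 2), 0 (Bl 3), 3 (Hw 3) or 2 (Ya 2). CRLF2 and MIR1803 passed in every fit with 1 array left out. ATP5E and PLBD1 were lost without Og 1 or Og 2 (adjusted p up to 0.0628 and 0.0895), CAPSL without Bl 1 or Bl 3 (up to 0.0664) and DCTD without Bl 1, Bl 3, Hw 3 or Ya 2 (up to 0.119). GIMD1 was lost without Bl 2, Bl 3, Hw 1, Hw 3, Ya 2 or Ya 3 (up to 0.126), and PLET1 in all fits but those without WL 2, WL 3, Og 1, Og 3, Bl 2 or Hw 2 (up to 0.143).

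Hwangbong had 15 specific features, 12 higher and 3 lower. PEX5L, a relative of the peroxisomal import receptor, rose by 1.5 ± 0.15, EEF1AKMT1, a methyltransferase of elongation factor eEF1A, by 1.21 ± 0.13, and FOLH1, a peptidase, by 1.12 ± 0.11 (adjusted p = 0.000458 each). ENOX1 fell by 1.15 ± 0.11 (adjusted p = 0.000458) and RALGPS1, an exchange factor for Ral GTPases, fell by 1.03 ± 0.13 (adjusted p = 0.0014). FOLH1 and NAALAD2 are related paralogs, so shared probe signal between them was not excluded. Against the mean of the other 4 breeds 192 features differed, 110 higher and 82 lower, with 2163 at an unadjusted p under 0.05. The count was 109 without Hw 1, 36 without Hw 2 and 59 without Hw 3, and all 5 named genes passed in every fit with 1 array left out.

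Hoengseong Yakdak had 9 specific features, 3 higher and 6 lower. SIDT1 rose by 2.36 ± 0.13 (adjusted p = 9.52e-07), ATRNL1 by 2.12 ± 0.17 (adjusted p = 2.88e-05) and DBNDD2 by 1.46 ± 0.12 (adjusted p = 3.16e-05). SLC7A10 fell by 2.16 ± 0.17 (adjusted p = 1.97e-05), ASPA, the aspartoacylase, fell by 1.94 ± 0.19 (adjusted p = 0.000184) and GVINP1, related to very large interferon-inducible GTPases, fell by 1.41 ± 0.16 (adjusted p = 0.000763). Against the mean of the other 4 breeds 183 features differed, 92 higher and 91 lower, with 2319 at an unadjusted p under 0.05. The count was 118 without Hw 3, 98 without Ya 1, 41 without Ya 2 and 98 without Ya 3, and all 6 named genes passed in every fit with 1 array left out.

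**Figure D4:**
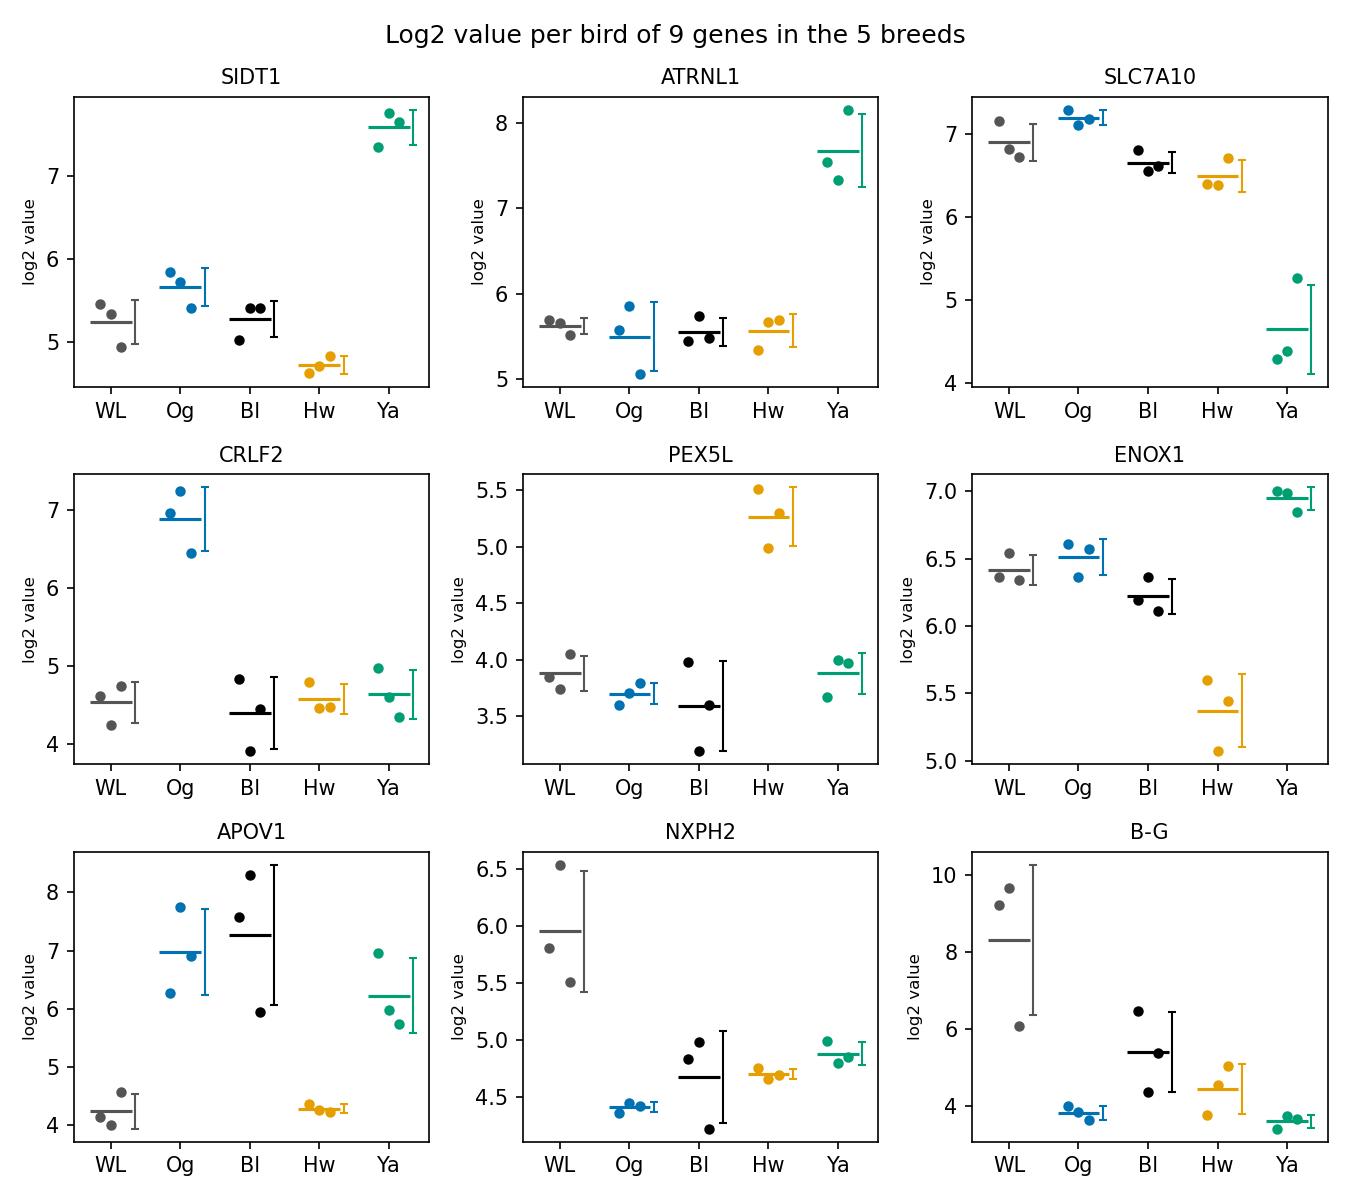
Log2 expression of 9 genes (vertical axes) in each bird (points) of the 5 breeds, with breed means (lines) and SD (bars). SIDT1 stands at 7.59 in Hoengseong Yakdak, CRLF2 at 6.88 in Yeonsan Ogye and PEX5L at 5.27 in Hwangbong, apart from the other breeds, and B-G is spread within White Leghorn at 8.31 ± 1.96.

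Of the 35 tested lists, 18 had no camera call in any comparison with White Leghorn. Melanocyte and pigment genes were among them: 0 of 20 measured genes passed in any comparison in limma, 1 in each breed had an unadjusted p under 0.05, and TYRP1 stood at 2.85 in White Leghorn and 2.45 in Yeonsan Ogye, levels not shown to be above background. The lowest adjusted p of this list was 0.373, in Hyunin Black. Yolk precursor genes had 9 measured members, of which APOV1 passed in Yeonsan Ogye, Hyunin Black and the native mean, and their lowest list p was 0.456. VTG1, at 4.02 to 4.41, and VTG2, at 3.67 to 3.83, were not shown to be above background in any breed, and the estrogen receptor ESR1 changed by -0.21 ± 0.33 in Yeonsan Ogye. APOV1 itself changed by 1.99 ± 0.50 in Hoengseong Yakdak (adjusted p = 0.0953) and by 0.05 ± 0.50 in Hwangbong (adjusted p = 0.983). In the other uncalled lists, the members past the threshold were LIPC, lower in Hwangbong and the native mean, NDUFA8, lower in Hwangbong, in Hoengseong Yakdak (-1.03 ± 0.18) and in the native mean (-0.71 ± 0.14), and STC2 in Hwangbong. SULT1B1, a sulfotransferase, fell by 1.74 ± 0.35 in Hoengseong Yakdak (adjusted p = 0.0442). SULT1B1 passed only without Og 3, Hw 1 or any Bl bird (adjusted p up to 0.129 otherwise). NDUFA8 was lost in Hoengseong Yakdak without WL 1, WL 2 or any Ya bird (up to 0.0757) and in the native mean in all fits but those without Og 1 or Bl 3 (up to 0.195).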

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

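Counts and calls were recomputed under the alternatives named with the methods, of which leaving out WL 1 and Og 1 together was chosen after seeing the data. Of 137 counts recomputed under alternatives other than leaving out 1 array, 94 stayed within 1.5 times the reported one and 43 did not; of 240 counts with 1 array left out, 59 did not. None of the gene and list calls changed sign under any of the alternatives run. Of the 61 gene calls, 55 were kept with trend and robust moderation, 60 with array weights, 56 after a further quantile normalisation, 58 after median centring and 61 with 1 feature per named gene. All 45 gene calls that could be tested without the lowest 33.3% of features were kept. Of the 37 list calls, 34 were kept after quantile normalisation and 30 without the lowest features. All 36 calls on lists of at least 10 genes were kept with those lists alone, which changes only the adjustment over the lists. After quantile normalisation the calls lost were fatty acid and triglyceride synthesis in Hwangbong and muscle and adipose markers in Hwangbong and the native mean.

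Array weights raised the counts against White Leghorn to 53 in Yeonsan Ogye, 48 in Hyunin Black, 264 in Hwangbong and 163 in Hoengseong Yakdak, the F test to 463, and the counts against the other 4 breeds to 14 in Yeonsan Ogye, 12 in Hyunin Black and 381 in Hwangbong. The lowest weights were 0.592 for WL 1 and 0.598 for Og 1. The cause of these rises was not tested. Using only the 6 arrays of the compared breeds, which leaves fewer arrays to estimate the spread, lowered the counts to 5, 5, 40 and 34 in the order Yeonsan Ogye, Hyunin Black, Hwangbong and Hoengseong Yakdak, and kept 13 of 36 gene calls. An unadjusted p under 0.05 with a 2-fold change, a criterion without control of false calls, gave 144, 139, 180 and 177 in that order. With 1 feature per named gene, fewer features were tested; 61 differed in Hoengseong Yakdak against White Leghorn, 51 in the native mean, 12 in Hyunin Black against the other 4 breeds and 120 in Hoengseong Yakdak against them. Adding a 1.5-fold minimum left 127 in Hwangbong against the other 4 breeds. Against the other 4 breeds, trend and robust moderation gave 15 in Yeonsan Ogye, and leaving out the lowest 33.3% of features gave 3 in Yeonsan Ogye and 10 in Hyunin Black; the cause was not tested.

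List calls rested on the preset correlation. With a correlation estimated per list, 1 list was called in Yeonsan Ogye, the EDN3 region, and 0 in Hyunin Black, Hwangbong, Hoengseong Yakdak and the native mean; fry likewise called 1 in Yeonsan Ogye and 0 in each of the others. The 36 calls lost with the estimated correlation had adjusted p between 0.433 and 0.838.

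Leaving out WL 1 and Og 1 together gave 14 features in Yeonsan Ogye, 57 in Hwangbong, 64 in Hoengseong Yakdak and 24 in the native mean, 16 in Yeonsan Ogye and 18 in Hyunin Black against the other 4 breeds, and 21 features shared by at least 2 comparisons with White Leghorn. It kept 31 of 61 gene calls and 26 of 37 list calls.

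Leaving out each array in turn gave ranges of 12 to 42 features for Yeonsan Ogye, 4 to 41 for Hyunin Black, 40 to 127 for Hwangbong, 24 to 112 for Hoengseong Yakdak and 16 to 93 for the native mean, all against White Leghorn, and 121 to 281 for the F test. Against the other 4 breeds the ranges were 7 to 13 for Yeonsan Ogye, 0 to 43 for Hyunin Black, 36 to 235 for Hwangbong and 41 to 184 for Hoengseong Yakdak. Shared features ranged from 18 to 50. Called lists ranged from 6 to 9 in Yeonsan Ogye, 6 to 11 in Hyunin Black, 6 to 13 in Hwangbong, 2 to 7 in Hoengseong Yakdak and 4 to 10 in the native mean. Of the 61 gene calls, 29 were lost without WL 2, 28 without WL 1 and 24 without WL 3, arrays that every comparison with White Leghorn shares.

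Replicate numbers were checked as a possible replicate block: 8 of 30 pairs of arrays with the same number had residual correlations above 0.1, and 8 of 15 arrays correlated best with an array of their own number. The median residual correlation was 0.0388 for pairs with the same number and -0.0151 for other pairs. Birds numbered 1 had the lowest array weight of their breed in all 5 breeds (0.592, 0.598, 0.676, 0.864 and 0.835 in the order WL, Og, Bl, Hw and Ya). A block shared by replicate number therefore stays open, and the main model leaves it out. With the block, 14 features differed in Yeonsan Ogye and 12 in Hyunin Black against the other 4 breeds, the other counts stayed within 1.5 times, and 55 of 61 gene calls and 36 of 37 list calls were kept. The calls lost were APOV1 and ZC3H12C in Yeonsan Ogye, ADAMTS17 in Hyunin Black, APOV1, C3ORF67 and LIPC in the native mean, and acute phase and complement in Hwangbong. The birds numbered 3 had the lowest list mean for heat shock in all 5 breeds (-0.052, -0.117, -0.308, -0.311 and -0.157 in the order WL, Og, Bl, Hw and Ya). For fatty acid and triglyceride synthesis the birds numbered 1 had the lowest list mean in every breed but Hwangbong. These means were -0.738, -0.004, -0.075 and -0.127 in WL, Og, Bl and Ya. The birds numbered 1 were likewise lowest for cholesterol synthesis and uptake in these breeds. The calls of both lists were kept with the block. Array background was not measured here, so signal over background limits the lowest features by an unknown amount.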

Other observations

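The tests of extra copies of the EDN3 region and of the interferon lists were chosen after the result was seen, whereas the other tests of the EDN3 region and those of neighbouring genes and other groupings were chosen before. HBAD, a globin of red blood cells, stood at 8.95, 8.85 and 9.06 in the 3 WL birds and between 9.23 and 11.01 in the 12 native birds, a change of 1.22 ± 0.27 in the native mean that did not pass (adjusted p = 0.0743). In Hyunin Black, HBAD changed by 1.49 ± 0.34, HBA1 by 1.10 ± 0.23, TSPO2 by 0.86 ± 0.18 and RHAG by 0.52 ± 0.18, while RHCE, a blood group protein, changed by -1.76 ± 0.33. RHCE in Hyunin Black and RHAG in White Leghorn stood at levels not shown to be above background. These 5 passed only when adjusted over the list alone, and 0 of 16 erythroid markers passed over all features. The erythroid list had its lowest camera adjusted p, 0.0682, in that breed.

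Some birds stood apart from the other birds of their breed. B-G stood at 9.21 and 9.65 in WL 1 and WL 2 and at 6.06 in WL 3, below Bl 1 at 6.45. COMTD1 stood at 8.53 and 9.02 in 2 WL birds and at 10.99 in the other WL bird, close to the native birds, which lay between 11.14 and 11.98. CAPSL, low in all 3 Bl birds, stood at 8.31 and 7.84 in Ya 1 and Ya 2 and at 6.28 in Ya 3. APOV1 stood at 7.58, 8.29 and 5.94 in the Bl birds and at 4.37, 4.26 and 4.23 in the Hw birds. Principal components of all features carried 14.3% and 12.6% of the variance in the first and second component, and WL 1 lay furthest out on the second, at 32.03 against 12.08 and 11.6 for WL 2 and WL 3. The same bird had the highest list means of the 15 for heat shock and handling stress (0.458) and for muscle and adipose markers (0.282), and the lowest for fatty acid and triglyceride synthesis (-0.738).

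The EDN3 region genes were higher in Yeonsan Ogye, with a mean change of 0.549, and in Hyunin Black, where the list was not called, 6 of 7 lay above 0, at the percentile 96.6 of the runs described below. A single array was excluded as the source: the list passed without each of the 15 arrays, with a highest adjusted p of 4.28e-04. The median change of 20 neighbouring genes was -0.0106 (standard error 0.128), below the bound of 0.274, which argues against a shift common to them all. These neighbours were taken at any level, and genes without liver signal could not show a shift. RBM38, at 0.99 ± 0.32, changed as much as the region's raised genes, while PCK1, at 1.63 ± 1.25, lay within 2 standard errors of 0. The measured genes between the region and PCK1, from NPEPL1 to C20orf85, had changes between -0.43 and 0.05. A shift of some neighbours stays open. The region's mean lay at the percentile 99.94 among 10808 runs of 7 neighbouring measured genes, which any local cause would give. Of the 7 genes, 4 lay above 0 by more than 2 standard errors. These 4, ZNF831, PRELID3B, ATP5E and TUBB1, lie next to each other among the measured genes. CTSZ and NELFCD, at the edge beside NPEPL1, changed by 0.10 and 0.12. EDN3, at 4.35 and 4.41, is not shown to be above background and counts neither way. Extra copies of the region therefore stay open, since no DNA was measured here, and a regulatory difference between the breeds stays open and untested.

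The interferon response list was called higher in Hyunin Black and in Hwangbong, calls that were lost with an estimated correlation (adjusted p = 0.564 and 0.721). In Hyunin Black the 33 leukocyte markers with a mean above 6, of which 2 are held by another list, had a median change of 0.161 (standard error 0.0656). A rise common to all leukocytes would need a median of at least 0.632, that of the interferon list, to be the whole cause. The value of 0.161 lay under 0.316, the bound set at 50% of that, by more than 2 standard errors. This argues against such a rise, but the standard error is over markers of the same birds and holds no spread between birds. The T-cell markers among them lay above 0 except CD5, at -0.22, with LCK at 0.06, CD3E at 0.374 and CD8A at 0.465. The T and NK cell list was also called higher in Hyunin Black, a call lost with an estimated correlation. More T cells therefore stay open. In Hwangbong the median of the 33 markers was 0.264 (standard error 0.0876) against 0.491 and a bound of 0.245, which leaves more leukocytes open. The most abundant of these markers were CTSB, at 11.57, 11.52 and 11.74 in White Leghorn, Hyunin Black and Hwangbong, C1QC at 10.80, 11.12 and 11.36, and CTSS at 10.54, 10.97 and 10.89. A response of single birds may explain the rise in Hyunin Black, where the list means of the 3 birds spanned 1.35 against a difference of 0.735 from White Leghorn, although all 3 lay above the highest WL bird. In Hwangbong the span was 0.446 against a difference of 0.529, which by itself does not decide on single birds. All 3 Hw birds lay above the highest WL bird, and the mean change stayed between 0.418 and 0.641 with any 1 array left out. These values argue against 1 bird as the sole source in Hwangbong. A breed difference stays open and untested in both breeds.

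Differing genes were also tested for lying beside each other in the genome. Of 169 differing genes with a known place, 10 had a differing neighbour, among them NAALAD2 beside FOLH1 and DCDC2 beside NRSN1. Random sets of as many genes gave a median of 10 and a 95th percentile of 18 (permutation p = 0.568 over 10000 sets), so these data show no excess that stretches of the genome would have to explain. Without neighbours that overlap or share the start of their names the number was 6, against a 95th percentile of 16, which leaves near-identical neighbours with nothing to explain.

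Other groupings of the same arrays were fitted for each count. For 3 birds against 3, the 10 splits are too few for a share under 0.05. The real and highest other counts of features were 35 and 2 in Yeonsan Ogye, 30 and 2 in Hyunin Black, 106 and 0 in Hwangbong and 101 and 0 in Hoengseong Yakdak, each real count being reached by 1 split, the real one. For the lists these pairs were 8 and 6 (reached by 1 split), 6 and 12 (6 splits), 12 and 12 (2 splits) and 4 and 8 (9 splits) in the same order.

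For comparisons of all 15 arrays, 100 assignments to 5 groups of 3 were fitted. Chance was excluded for the F test, with 293 features against a highest other of 7. The native mean gave 79 features against 70, and the shared features were 40 against 17. In each, 1 assignment, the real one, reached the real count. The assignments mix the birds of all breeds, so they ask whether any breed differs at all. They cannot decide whether the native mean or the sharing exceeds what 1 deviating breed gives. The 70 and the 17 came with the 3 Hw arrays in the place of White Leghorn. Without WL 1 the native mean gave 16 features and 18 were shared, although that fit holds fewer arrays than the assignments. Against the other 4 breeds the real and highest other counts were 7 and 5 in Yeonsan Ogye, 192 and 80 in Hwangbong and 183 and 3 in Hoengseong Yakdak. Each real count was reached by 1 assignment. For the same reason these counts cannot decide on a single breed. The 80 in Hwangbong came from the 3 Hw arrays themselves, with the birds of the other breeds mixed. In Hyunin Black 4 assignments reached the 6 features, the real one included, a share only narrowly under 0.05. The highest other gave 43, and the real count was 0 without Bl 3, so chance is not called excluded for that breed either. Chance was not excluded for the 7 lists called in the native mean, a number reached by 51 assignments with a highest other of 14. The assignments behind 70, 7, 43, 80 and 17 kept the 3 Hw arrays together, which points to the breed structure of the samples.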
